A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

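Messenger RNA was measured in 6 cultures of Saccharomyces cerevisiae, 3 of strain IMF17 and 3 of strain IMX2109. Per the labels' protocols, each strain was started from a frozen stock, moved to fresh medium in biological triplicate, and grown aerobically in a 500 mL shake flask holding 100 mL of selective minimal glucose medium to an optical density at 660 nm of 8, in mid-exponential phase. Per the labels' protocols, cultures were sampled into liquid nitrogen, RNA was extracted with hot phenol, and libraries were made with a stranded mRNA kit and sequenced on an Illumina instrument. Groups and replicate numbers were taken from the sample titles.

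The deposited values are FPKM, reads scaled by gene length and by the total of counted reads, with 1 table per library and 5703 features in each. Per the submitters' processing notes, STAR 2.5.4a, SAMtools, featureCounts, edgeR and DESeq2 were used by the authors. The roles of these tools, their settings, the treatment of reads that map to more than 1 place, the use of strand in counting and any filter on features are not given in the sources used here. Per the file headers, features carry coordinates on a polished assembly of strain IMF17 that includes its neochromosome and the 2-micron plasmid, so reads of both strains were counted on the gene models of IMF17. A sequence that differs between the strains can therefore lose reads of IMX2109. All positions below are on that assembly. Gene names came from the tables, and 5497 features were matched by locus tag to the S. cerevisiae R64 reference annotation, which served only for names. The other 206 features were kept under the names in the tables, 82 of them off the neochromosome. A name was shared by more than 1 feature for 294 features, and values of such genes, of duplicated ribosomal protein and histone genes, and of near-identical families such as MAL12 with MAL32 and PHO5 with PHO3 are uncertain, because reads can be split between copies.

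Multiplying the deposited FPKM by gene length gave whole multiples of 1 read's worth for 100% of values within a tolerance of 0.01 reads, which gave back the number of reads per feature. Totals ranged from 14696540 to 18801158 reads per library. A count of 0 was given a floor of 3 reads over the group. Floors cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules. Replicate libraries of a strain differed by 3.15 to 18.1 times the sampling noise (chi-square per degree of freedom over genes), so no library was a copy of another. The widest pairs were those of IMX2109 replicate 3 with replicates 1 and 2 of that strain, at 18.1 and 8.52. The other pairs gave 3.15 to 7.22.

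The comparison was IMF17 against IMX2109. Features with a mean FPKM of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model with a trended prior variance, two-sided) on log2(FPKM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low genes, and folds in the text are ratios of mean FPKM where called folds. All adjusted p-values come from limma. Gene lists, 44 in number and written before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01 when they had at least 4 tested members, which left 42, and again with an estimated correlation and with fry. The genes of each nuclear chromosome were tested the same way. The joint level of the 13 major glycolytic and fermentative genes was their share of the summed FPKM, compared by an exact permutation test. edgeR and DESeq2 were not run, because the deposited unit is FPKM, although they had been foreseen for the case of recoverable reads. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

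The choice of test, lists, alternatives and named genes was made before the data were examined. Named genes were the 13 glycolytic genes, the genes used as markers and features outside the reference annotation, the 12 largest rises and 12 largest falls among genes past the threshold whose libraries did not overlap between strains and whose higher mean was at least 10 FPKM, and up to 4 members with the smallest p of each described list. The 12 largest rises were all on the neochromosome or the 2-micron plasmid, so the largest rises on the nuclear chromosomes were added after the data were seen, as were a few further genes given as examples. The other settings tried were other pseudocounts and filters, rescaling by median ratio or to TPM, robust variances, the replicate number as a block, and leaving out each library. Rescaling on reads of nuclear chromosomes and limma-voom on the recovered reads were added after the data were seen. The test was checked on simulated reads built on these libraries, with 5431 genes tested and 200 changed. It recovered 86% of genes changed 1.25-fold, 98% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, with 50 genes at each size and 6.86% of calls false. With no change simulated it called 0 genes and 0 of 42 lists. Simulated genes varied independently of each other, at a single dispersion of 0.00153. The simulation therefore does not test lists whose genes vary together, such as ribosomal proteins (estimated correlation 0.742) and ribosome biogenesis (0.814). Rises and falls were simulated in equal number, with no difference in read composition between the strains built in. The 6.86% therefore does not cover calls that depend on scaling. The minor paralogs of the glycolytic genes, such as TDH1, ENO1 and PDC5, were not analysed here.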

Results

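Transcript levels were compared between 2 yeast strains that carry the genes of glycolysis and alcoholic fermentation in different places. IMF17 expresses them only from a neochromosome, an added synthetic chromosome, and IMX2109 expresses them from its native genome. The question was how moving the pathway to the neochromosome bears on its expression and on that of other genes. Each strain was represented by 3 cultures, with 14999412 to 15914985 counted reads per library in IMF17 and 14696540 to 18801158 in IMX2109. The first principal component of log2(FPKM + 1) held 93.1% of the variance and separated the strains. It included 58 neochromosome features outside the yeast annotation and 4 genes of the 2-micron plasmid, almost all without reads in IMX2109. How much of the 93.1% these features carry was not computed.

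Of the 13 major glycolytic and fermentative genes, 12 rose in IMF17 and PFK1 fell (limma, the same 12 and 1 adjusted over the list alone). ADH1, the main alcohol dehydrogenase of fermentation, stood at 9312 ± 366 FPKM in IMF17 and 2005 ± 177 FPKM in IMX2109 (SD, n = 3), a 4.64-fold difference (limma adjusted p = 2.02e-10). TDH3, glyceraldehyde-3-phosphate dehydrogenase, reached 21508 ± 667 against 14852 ± 1077 FPKM, 1.45-fold higher in IMF17. PFK1 and PFK2, the subunits of phosphofructokinase, went opposite ways, with PFK2 at 654 ± 3.94 against 428 ± 7.72 FPKM and PFK1 at 408 ± 5.98 against 532 ± 30.9 FPKM. On the log2 scale PFK2 rose by 0.61 ± 0.03 (SE, limma adjusted p = 1.49e-07) and PFK1 fell by 0.38 ± 0.05 (limma adjusted p = 8.69e-05).

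Of the other rises, PYK1 was 1.55-fold higher, HXK2 1.43-fold, PGK1 1.42-fold, TPI1 1.39-fold, ENO2 1.35-fold, FBA1 1.32-fold, PGI1 1.31-fold and GPM1 1.27-fold. PDC1, pyruvate decarboxylase, was 1.09-fold higher (8136 ± 245 against 7442 ± 188 FPKM, limma adjusted p = 0.0378), and its call was lost under median-ratio rescaling (limma adjusted p = 0.0704), with the replicate number as a block (0.0582) and without any one of IMF17 replicates 1, 2 and 3 and IMX2109 replicate 2 (limma adjusted p from 0.062 to 0.229). In these settings the log2 fold change of PDC1 was 0.195, 0.129 and 0.105 to 0.147, against 0.129 in the main fit. The 13 genes lie side by side on the neochromosome, from FBA1 at 32673 to PDC1 ending at 66483. As a list they were higher relative to other genes (median log2 fold change 0.48, limma camera adjusted p = 2.59e-10), a call not kept with an estimated correlation (limma camera adjusted p = 0.186 with an estimated correlation). Together the 13 genes made up 11.8 ± 0.332% of the summed FPKM in IMF17 and 8.21 ± 0.369% in IMX2109 (SD, n = 3). All 3 IMF17 libraries lay above all 3 IMX2109 libraries, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 can give.

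**Figure D1:**
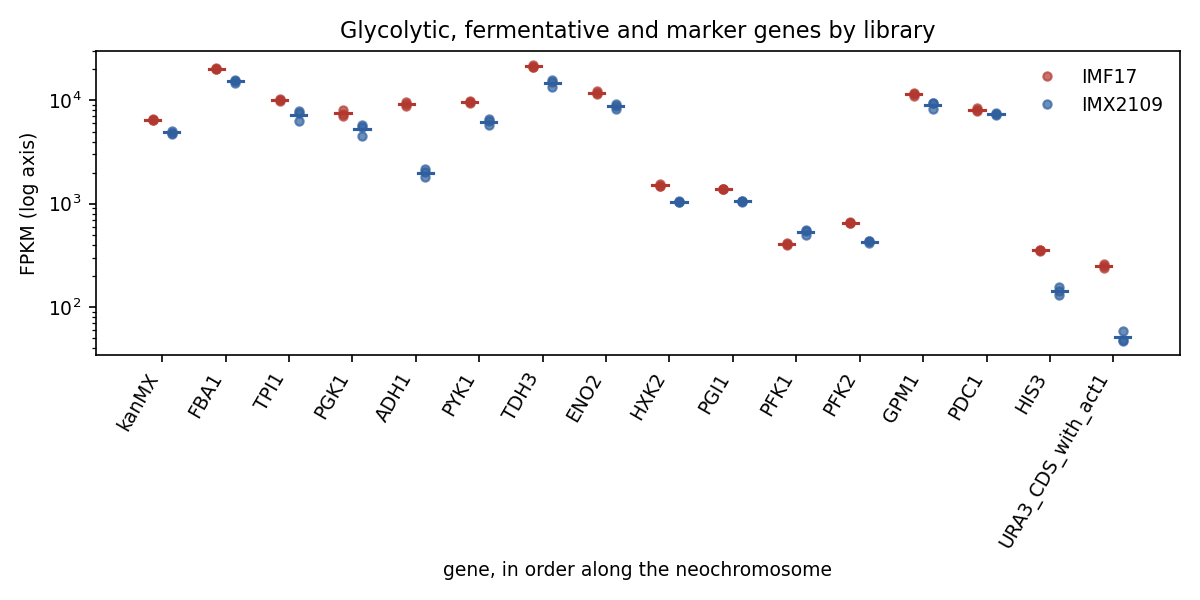
FPKM of the 13 glycolytic and fermentative genes and 3 marker genes in each library, on a log axis, in their order along the neochromosome, with points for libraries and bars for the mean of each strain. ADH1 shows the widest gap of the 13 genes at 4.64-fold, and PFK1 is the gene of the 13 with IMX2109 above IMF17.

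Marker features on the neochromosome held reads in both strains and were higher in IMF17. The reads of IMX2109 were counted on the IMF17 assembly, and which locus of IMX2109 they come from was not tested. The resistance marker kanMX was 1.33-fold higher, HIS3 of histidine synthesis 2.48-fold higher (356 ± 4.90 against 144 ± 13.4 FPKM), and the feature URA3_CDS_with_act1, 1214 bases long, 4.90-fold higher (249.8 ± 12.2 against 51.0 ± 6.28 FPKM; limma adjusted p = 1.06e-09). What the act1 part of that feature holds is not given in the sources used here. The URA3 feature on chromosome 5, 597 bases long, did not pass the test, at 7.27 FPKM in IMF17 and 7.34 FPKM in IMX2109. CAN1, the arginine permease on chromosome 5 (32751 to 34523), rose 11.1-fold, from 15.1 ± 0.858 to 167 ± 4.59 FPKM. Its neighbours did not rise: AVT2 fell by 0.29 and NPR2 did not pass the test (log2 fold change -0.14). Of the 14 tested features of the list of markers and integration sites, 2 rose and 6 fell (limma, the same counts adjusted over the list alone), the falls being 3 features named LEU2 and 1 each of HO, ADE2 and MET17. TRP1, AMD2 and DUR3 did not pass.

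The neochromosome also carries 108 features outside the yeast reference annotation, many with names of bacterial genes. They took 1.74 ± 0.0426% of the reads in IMF17 (SD, n = 3) and 9 reads in all in IMX2109, of which 8 were on hypothetical_protein_9. Of the 108, 97 had more than 3 reads over the IMF17 libraries and 106 had 0 reads in IMX2109. The feature hypothetical_protein_9 did not pass the test. Most were low: the median was 2.49 FPKM, against 51.1 FPKM over 5557 nuclear features, and 23 reached 10 FPKM. A pair of them stood far above the rest. With 14509 ± 444 FPKM, hypothetical_protein_26 (133751 to 134428) ranked 3 among the 5703 features of IMF17, and hypothetical_protein_16 (99726 to 100448), at 9583 ± 174 FPKM, ranked 9. The latter had 0 reads in IMX2109 and was at least 117678-fold higher in IMF17 against the floor of 3 reads over the group. What either encodes is not given in the sources used here. Next came hypothetical_protein_15 at 299 FPKM, cspE at 282 FPKM, hypothetical_protein_18 at 199 FPKM, rmf at 123 FPKM and hspQ at 105 FPKM. A stretch of 12.8 kb from 118510 to 131296 held 15 features with no more than 0.469 FPKM each.

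**Figure D2:**
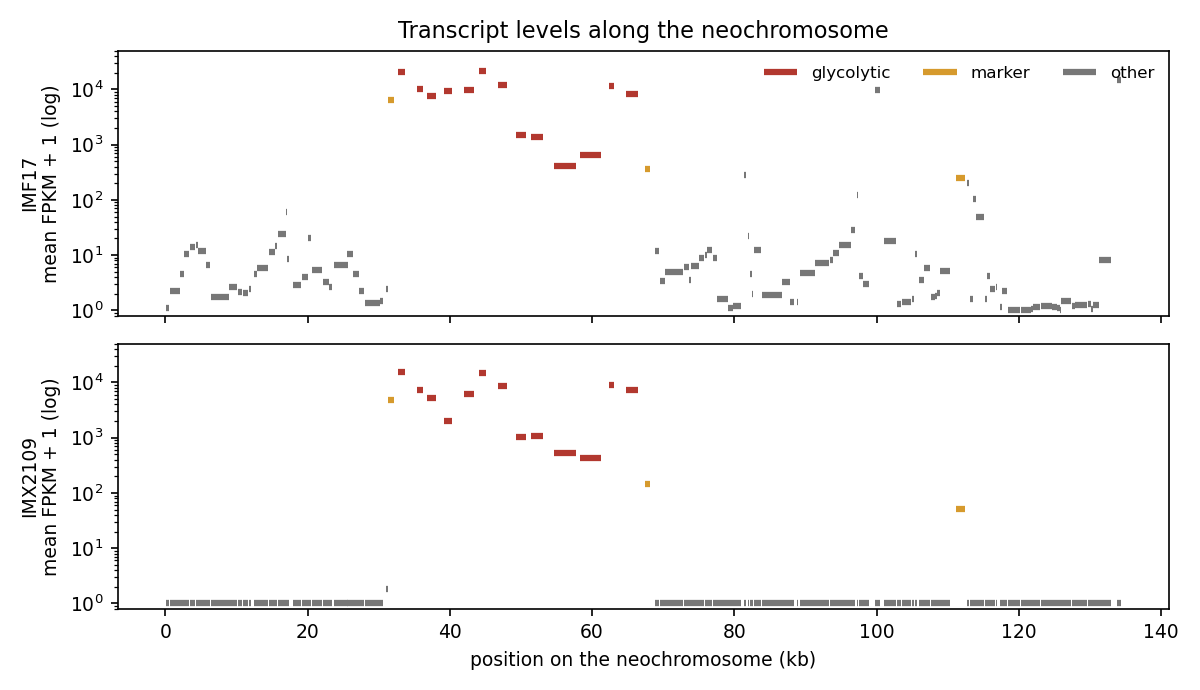
Mean FPKM + 1 of each feature of the neochromosome (log axis) against its position in kb, for IMF17 above and IMX2109 below, with glycolytic genes, markers and other features in separate colours. In IMX2109 the other features lie at the base of the axis, with 9 reads in all over 108 features.

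The 2-micron plasmid, a natural multicopy plasmid of yeast, was detected in IMF17 and not in IMX2109. FLP1, REP1 and REP2 had 1170, 17590 and 18862 reads in the IMF17 libraries and 0 reads in the IMX2109 libraries, out of 51549931, which allows a share of up to 5.82e-06%. The highest, REP2, a gene of plasmid partitioning, stood at 454 ± 15.9 FPKM in IMF17, at least 6873-fold higher than the floor of 3 reads over the IMX2109 group.

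Across the transcriptome, 2029 of 5425 tested features changed, 654 higher and 1375 lower in IMF17 (limma). The balance depended on scaling: it was 882 higher and 639 lower after median-ratio rescaling, and 1030 higher and 480 lower when libraries were rescaled on reads of nuclear chromosomes. Nuclear features held 84.6 ± 0.323% of the counted reads in IMF17 and 90.4 ± 0.519% in IMX2109 (SD, n = 3). FPKM is scaled to all counted reads, so this difference by itself lowers nuclear values in IMF17. The excess of falls over rises is therefore not to be read as a general fall of nuclear genes. Most changes were small, and 130 features changed by at least 2-fold, of which 129 rose. On the nuclear chromosomes 65 rose and 1, ATR1, fell by that much. ATR1 lay at the cut, with a log2 fold change of -1.01. The count of such falls was 0 with a pseudocount of 5 and under median-ratio rescaling, nuclear rescaling and voom. It was also 0 without any one of IMF17 replicates 1 and 2 and IMX2109 replicate 3. The 3 values of each strain did not overlap for 49.6% of features, taken on FPKM without rescaling. For a single feature the chance of this is 10%. Features share the same 6 libraries and their scaling, so 10% is no baseline for the share. The largest nuclear rises were in MAL12, THI4, CAN1, YGP1, MAL11, HSP30, PHO5, PIR3, HSP12, CYC7, EGO4 and YRO2, from 3.67 down to 2.01 on the log2 scale. The largest falls were in ATR1, a multidrug efflux gene (2.02-fold lower), ATO3, SFG1, SPS4, YFL057C, FET3, HXT4, SHM2, SNO1, BAP2, CIT2 and GCV2, the last by 0.58 on the log2 scale. Of the 42 lists, 22 passed limma's camera with the preset correlation, 13 up and 9 down, and 0 passed with an estimated correlation (10 at an unadjusted p under 0.05; fry called 29). Groupings of the 6 libraries that mixed the strains, each keeping part of the strain difference, called 0 genes (at most 204 at an unadjusted p under 0.05) and 3 to 20 lists. In them the strain difference widens the spread within groups, so the 0 genes are no baseline for the 2029.

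Genes of the general stress response rose in IMF17, with 21 of 25 higher, 2 lower and 2 not past the test (21 higher and 3 lower adjusted over the list alone). YGP1, a secreted glycoprotein made on nutrient limitation, rose 9.13-fold to 283 ± 26.8 FPKM, HSP12, a membrane stress protein, rose 4.62-fold to 623 ± 33.6 FPKM, and SED1 and DDR2 rose 2.35-fold and 2.64-fold. The list passed limma's camera (adjusted p = 1.85e-15; adjusted p = 0.145 with an estimated correlation). Among genes of trehalose and glycogen metabolism 15 of 21 rose and 0 fell (15 and 1 adjusted over the list alone), led by the glycogen phosphorylase GPH1 at 4.55-fold, with TSL1 at 2.19-fold and PGM2 rising by 0.96 on the log2 scale (limma camera adjusted p = 1.2e-09; adjusted p = 0.255 with an estimated correlation). Of 10 genes of glycerol metabolism 7 rose and 2 fell (7 and 2 adjusted over the list alone), among them GPP2 at 2.75-fold and GPD1, which commits carbon to glycerol, at 2.04-fold, with falls in FPS1 and GPD2 (limma camera adjusted p = 6.93e-05; adjusted p = 0.186 with an estimated correlation). Under median-ratio rescaling, nuclear rescaling and voom and without IMF17 replicate 2 the falls of FPS1 and GPD2 were no longer called. Heat shock chaperones split, with 8 of 27 higher and 3 lower (8 and 3 adjusted over the list alone; 7 and 5 without IMF17 replicate 1). HSP30 rose 7.12-fold, HSP26 3.84-fold and SSE2 2.41-fold, while SSB1 and SSB2, which act on nascent chains, fell (limma camera adjusted p = 0.00803; adjusted p = 0.548 with an estimated correlation). That list call was lost without IMF17 replicate 1 (limma camera adjusted p = 0.0701) and without IMX2109 replicate 3 (0.0565). Of 43 cell wall genes 18 rose and 10 fell (18 and 10 adjusted over the list alone), with PIR3 up 5.20-fold and CWP1 up 2.32-fold, and with falls in the daughter-cell separation genes EGT2 and DSE4 (limma camera adjusted p = 0.000854; adjusted p = 0.137 with an estimated correlation).

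Genes of phosphate acquisition rose, 12 of 20, with 2 lower (13 and 2 adjusted over the list alone; 11 and 1 without IMF17 replicate 1 and 14 and 1 after nuclear rescaling). PHO5, the repressible acid phosphatase, rose 5.43-fold to 186 ± 8.26 FPKM, PHM8 rose 2.83-fold and the transporter PHO84 2.06-fold, while the regulator PHO4 and the low-affinity transporter PHO90 fell (limma camera adjusted p = 1.28e-08; adjusted p = 0.0616 with an estimated correlation). Of 20 genes of vitamin B1 and B6 metabolism 12 rose and 2 fell (12 and 2 adjusted over the list alone). THI4, of thiamine synthesis, rose from 15.1 ± 0.874 to 197 ± 10.1 FPKM and PHO3 rose 3.18-fold, while SNZ1 and SNO1 fell (limma camera adjusted p = 1.86e-08; adjusted p = 0.0616 with an estimated correlation). In the list of galactose and maltose use 9 of 20 features rose and 0 fell (9 and 1 adjusted over the list alone; 4 higher with a filter at 10 FPKM), and these were maltose and isomaltose genes. MAL12, a maltase, rose 14.9-fold and MAL11, a maltose transporter, 8.78-fold, whereas GAL1 did not pass (log2 fold change -0.03) (limma camera adjusted p = 1.15e-07; adjusted p = 0.12 with an estimated correlation). Reads of MAL12 can be exchanged with MAL32, and their summed reads were 15.3-fold higher in IMF17.

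Genes of the respiratory chain and ATP synthase rose by small amounts, 29 of 39, with 0 lower (31 and 0 adjusted over the list alone; 19 higher without IMF17 replicate 2). CYC7, the minor cytochrome c, was the exception in size at 4.78-fold, with NDI1 at 1.62-fold and RIP1 at 1.19-fold (limma camera adjusted p = 1.16e-13; adjusted p = 0.142 with an estimated correlation). Of 23 genes of the tricarboxylic acid cycle 12 rose and 1 fell (12 and 1 adjusted over the list alone; 10 and 3 without IMX2109 replicate 1), including CIT3 at 1.68-fold and MDH1 at 1.40-fold (limma camera adjusted p = 5.28e-06; adjusted p = 0.246 with an estimated correlation). In the list of gluconeogenesis and the glyoxylate cycle 9 of 14 rose and CIT2 fell (9 and 1 adjusted over the list alone; 4 and 1 with a filter at 10 FPKM). MLS1, malate synthase, rose 3.36-fold, JEN1 2.55-fold and SFC1 3.06-fold, all from no more than 2.30 FPKM, and FBP1 and PCK1, the enzymes specific to gluconeogenesis, did not pass (log2 fold changes 0.16 and 0.10) (limma camera adjusted p = 3e-05; adjusted p = 0.186 with an estimated correlation). Hexose transport genes went both ways, 4 of 16 higher and 4 lower (4 and 4 adjusted over the list alone). HXT7 rose 2.85-fold and HXT1 1.33-fold, and HXT4 and HXT3 were 1.62-fold and 1.20-fold lower.

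Genes of protein synthesis and of amino acid synthesis fell. Of 127 features of cytosolic ribosomal proteins 109 fell and 0 rose (118 and 0 adjusted over the list alone), with a median log2 fold change of -0.22; 38 fell after median-ratio rescaling, 51 after rescaling on nuclear reads and 51 with voom. RPL31B and RPS26B, among the widest, were each 1.31-fold lower (limma camera adjusted p = 2.27e-15; adjusted p = 0.501 with an estimated correlation). Of 72 genes of ribosome biogenesis 45 fell and 0 rose (49 and 0 adjusted over the list alone; 26 fell after rescaling on nuclear reads), with RRP1 1.35-fold lower (limma camera adjusted p = 2.38e-07; adjusted p = 0.548 with an estimated correlation). Fry did not call this list (fry adjusted p = 0.0654). Its lower count was 30 without IMF17 replicate 1 and 63 without IMF17 replicate 3. A grouping that mixed the strains, and so kept part of their difference, gave it a lower camera adjusted p, 1.45e-21. Amino acid synthesis genes under the activator Gcn4 fell, 41 of 56, with 2 higher, BAT2 and the marker HIS3 (47 and 2 adjusted over the list alone; 27 fell after median-ratio rescaling and 24 after rescaling on nuclear reads). LYS1, of lysine synthesis, was 1.47-fold lower and LEU1 1.37-fold lower (limma camera adjusted p = 3.66e-08; adjusted p = 0.142 with an estimated correlation). Of 31 genes of sulfur and methionine metabolism 24 fell and 0 rose (26 and 0 adjusted over the list alone; 16 after median-ratio rescaling and 14 after rescaling on nuclear reads), among them the sulfate permease SUL1 at 1.48-fold lower and MET6 at 1.28-fold lower (limma camera adjusted p = 7.66e-06; adjusted p = 0.145 with an estimated correlation). Of 12 histone genes and regulators 10 fell, the histones by 0.17 to 0.45 on the log2 scale, with HTA2 1.34-fold lower (10 adjusted over the list alone; limma camera adjusted p = 6.11e-05; adjusted p = 0.233 with an estimated correlation).

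**Figure D3:**
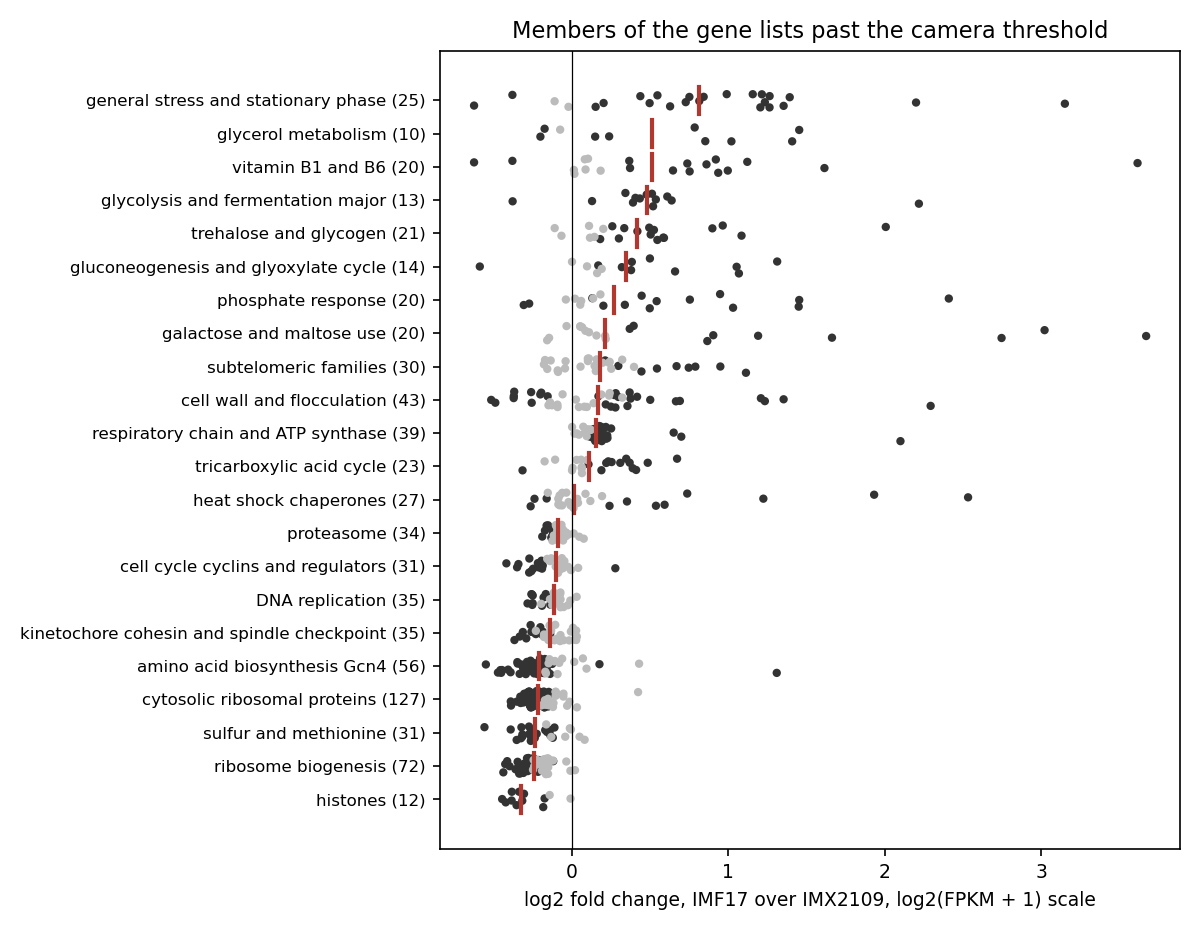
Log2 fold change, IMF17 over IMX2109 on the log2(FPKM + 1) scale, of each tested member of the 22 lists past the camera threshold, with the number of members beside each list. Dark points passed the gene-level test, grey points did not, and the bar is the median; the highest median, 0.81, is that of the general stress genes, and ribosomal proteins lie at -0.22.

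Several lists of growth and division lay at the edge of the test. Among all 5425 tested features 1375 were lower and 654 higher, and the lower counts for replication and the proteasome are near that share. Kinetochore, cohesin and checkpoint genes had 14 of 35 lower and 0 higher (15 and 0 adjusted over the list alone), cell cycle regulators 12 of 31 lower and 1 higher (12 and 1), DNA replication genes 10 of 35 lower (9 adjusted over the list alone) and proteasome genes 10 of 34 lower (9 adjusted over the list alone). Their limma camera adjusted p-values were 0.0281, 0.0298, 0.0399 and 0.0351, and with an estimated correlation the adjusted p-values were 0.548, 0.564, 0.548 and 0.233. After median-ratio rescaling the number of lower genes was 7, 9, 4 and 0, and after nuclear rescaling 4, 6, 1 and 0. With a library left out it went down to 8 for the kinetochore list, 4 for replication and 5 for the proteasome. Without IMX2109 replicate 3 the kinetochore, cell cycle and replication calls were lost (limma camera adjusted p = 0.0685, 0.0757 and 0.103), without IMF17 replicate 3 those of the cell cycle and proteasome (0.067 and 0.0728), without IMX2109 replicate 2 that of the proteasome (0.0509), and without IMF17 replicate 1 or 2 that of replication (0.0556 and 0.0566). All 4 calls were lost with a filter at 10 FPKM (limma camera adjusted p = 0.0661, 0.0661, 0.0875 and 0.0719), that of replication also on the TPM scale (0.0629), and that of the proteasome also under median-ratio rescaling, nuclear rescaling and voom (0.325, 0.522 and 0.342). Members of subtelomeric families, near-identical copies whose reads may be shared, had 9 of 30 higher (9 adjusted over the list alone; 13 after median-ratio rescaling, 17 of 32 after nuclear rescaling and 4 of 18 with a filter at 10 FPKM; limma camera adjusted p = 7.01e-05; adjusted p = 0.142 with an estimated correlation).

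The remaining lists did not pass limma's camera, and their counts are to be read beside 1375 lower and 654 higher among all 5425 tested features. Iron regulon genes had 13 of 34 lower and 1 higher (10 and 4 after median-ratio rescaling), with FET3, a multicopper oxidase of iron uptake, 1.64-fold lower (camera adjusted p = 0.0937, past the threshold under median-ratio rescaling, nuclear rescaling and voom). Acetate and ethanol genes had 6 of 13 higher and 3 lower, and the list lay just outside the threshold (camera adjusted p = 0.0501) and inside it under 8 other settings, 4 of them with a library left out. The pentose phosphate list went both ways, 5 of 13 higher and 6 lower (5 and 3 after median-ratio rescaling), with TKL2 up 4.04-fold and NQM1 up 3.67-fold and with ZWF1 1.16-fold and GND1 1.18-fold lower. Nitrogen catabolite repression genes had 4 of 30 higher and 13 lower (4 and 14 adjusted over the list alone; 8 lower after median-ratio rescaling), CAN1 being the widest rise, and oxidative stress genes had 8 of 25 higher and 5 lower (9 and 5; 4 and 4 without IMF17 replicate 1 or 2, 9 and 3 after median-ratio rescaling). Ergosterol genes had 9 of 26 lower and 0 higher (9 and 0), and lipid synthesis genes 10 of 24 lower and 2 higher (11 and 2), with 1 and 3 lower after median-ratio rescaling, lipid synthesis at 5 higher and 2 lower after nuclear rescaling, and ergosterol at 4 lower without IMF17 replicate 2 or IMX2109 replicate 2. Uracil synthesis genes had 6 of 15 lower and 2 higher, histidine synthesis 3 of 7 lower and HIS3 higher, the unfolded protein response 4 of 22 lower, multidrug resistance 3 of 19 higher and 2 lower, meiosis 4 of 30 higher and 2 lower, haploid-specific genes 5 of 21 lower and 2 higher, and zinc and copper genes 2 of 12 higher and 2 lower. Adjusted over the list alone the lower counts were 7, 4, 1, 1, 2, 5 and 3. The unfolded protein response had 0 lower under median-ratio rescaling, nuclear rescaling and voom, and 1 lower without IMF17 replicate 2 or IMX2109 replicate 2. After median-ratio rescaling multidrug resistance had 6 higher and 1 lower, haploid-specific genes 2 and 2, and zinc and copper genes 4 and 1. Multidrug resistance also had 6 higher and 1 lower without IMX2109 replicate 3. Haploid-specific genes had 1 higher and 2 lower without IMX2109 replicate 2, and 1 and 3 without IMF17 replicate 2 or 3. Zinc and copper genes had 0 higher without IMF17 replicate 2 or IMX2109 replicate 2. Meiosis genes had 7 higher and 1 lower after nuclear rescaling, 2 and 3 without IMF17 replicate 2, and 2 and 2 without IMX2109 replicate 1. Genes of the response to DNA damage had 0 of 24 higher and 5 lower (2 lower adjusted over the list alone). They had 1 higher and 1 lower under median-ratio rescaling, nuclear rescaling and voom, and 2 lower without any one of IMF17 replicates 2 and 3 and IMX2109 replicate 2. Silencing and telomere genes had 0 of 18 called. The mating-type genes gave STE2, the receptor of MATa cells, at 542 FPKM in IMF17 and 547 FPKM in IMX2109 (log2 fold change -0.01, above 0 under median-ratio rescaling, nuclear rescaling and voom), and STE3, the receptor of MATalpha cells, at 10.3 FPKM in IMX2109 with a log2 fold change of 0.08, neither past the test. MF(ALPHA)1, an alpha-factor gene, rose from 3.12 to 11.8 FPKM, 1 of 2 rises among 4 tested genes specific to MATalpha cells. SAG1 of that list fell (log2 fold change -0.21, limma adjusted p = 0.0473), a call lost under most other settings, among them median-ratio rescaling (limma adjusted p = 0.11) and the omission of any one library but IMX2109 replicate 1. As for whole chromosomes, 0 of 16 nuclear chromosomes passed limma's camera (0 at an unadjusted p under 0.05), and their median log2 fold changes ran from -0.09 to -0.04.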

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

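Rescaling on nuclear reads and voom on recovered reads were chosen after the data were seen, the other settings before. The number of changed genes lay between 1455 and 2017 with each library left out, features changed by at least 2-fold between 121 and 138, called lists between 18 and 23, called chromosomes stayed at 0, and the difference in glycolytic share lay between 3.35 and 3.71 percentage points. Features changed by at least 2-fold came to 86 with a pseudocount of 5, which shrinks folds of low genes, and to 68 with a filter at 10 FPKM, which removes genes. Called lists fell to 0 with an estimated correlation, also where the estimate lay below the preset 0.01, and the cause was not tested. The higher and lower calls were 908 and 648 with voom, and 1292 of the 2029 calls were shared with median-ratio rescaling and 1134 with nuclear rescaling. As for pairing, the deviations of same-numbered cultures correlated at 0.0969, -0.0187 and 0.192 across genes, and the numbers were not taken to pair the cultures. IMF17 replicate 1 correlated best with IMX2109 replicate 2 (0.132) and IMF17 replicate 2 with IMX2109 replicate 1 (0.0652). With the replicate number as a block 685 genes were higher and 1517 lower, 2202 in all, and 23 lists were called. Of lists past the threshold, the heat shock median came to -0.0361 without IMF17 replicate 1 and -0.0146 without IMX2109 replicate 3, and the proteasome median to 0.00963 under nuclear rescaling, signs opposite to those reported. Named genes that changed sign and lists whose camera direction turned lay outside the threshold. Median-ratio rescaling shifted log2 fold changes upward by 0.0663 before the pseudocount, more than TRP1 (-0.0296) and the URA3 feature on chromosome 5 (-0.0175) lay below 0. The cause of the other turns was not tested. Under median-ratio rescaling, nuclear rescaling and voom, STE2 came to 0.0519, 0.0817 and 0.0532, STE6 to 0.00116, 0.0307 and 0.00127, TRP1 to 0.0359, 0.0655 and 0.0358, and that URA3 feature to 0.0406, 0.0679 and 0.0447, and AMD2 came to 0.0102 under nuclear rescaling. With each library left out TRP1 ranged from -0.0545 to 0.00664 (above 0 without IMF17 replicate 3) and the same URA3 feature from -0.0938 to 0.0705 (above 0 without IMF17 replicate 1 and without IMX2109 replicate 1). Medians of lists whose camera direction turned were -0.139 with a filter at 10 FPKM and 0.105 under nuclear rescaling for hexose transport, -0.154 with that filter for nitrogen catabolite repression and -0.0428 with no filter for silencing. With each library left out these medians ranged from -0.0733 to -0.0226 for zinc and copper (turned without IMF17 replicate 3), from -0.13 to -0.0772 for nitrogen catabolite repression (turned without IMF17 replicate 3 and without IMX2109 replicate 1) and from -0.0942 to 0.00773 for silencing (turned without the same libraries). The planned share with minor paralogs had no value, and the planned edgeR and DESeq2 fits were not run, with voom in their place. Depth limits low features, tested ones included: hypothetical_protein_9 rested on 12 reads in IMF17 and 8 in IMX2109. Power by level was not measured.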

Other observations

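The other groupings of the libraries, leaving out each library and median-ratio rescaling were planned before the data were seen. Nuclear rescaling and the other tests in this part were chosen after the result was seen, as were the bounds to which leaving out libraries and rescaling were held. Several genes of purine and one-carbon metabolism fell in IMF17. A list was drawn up after falls in SHM2, GCV1, GCV2 and ADE1 had been seen, and a first version of 13 genes presented as unseen gave a camera p of 8.99e-05. It held ADE2, ADE12 and LPD1, whose values had in fact been seen, so these were taken out. LPD1 was the 1 gene of the first version that rose (log2 fold change 0.11, limma adjusted p = 0.0419), and ADE2 and ADE12 fell. Of the 10 left, ADE4, ADE5,7, ADE6, ADE8, ADE13, ADE17, ADE3, MTD1 and GCV3 fell and ADE16 did not pass (limma), with a median log2 fold change of -0.42. After median-ratio rescaling 8 of the 10 were lower and 1 higher. A joint fall may be a hypothesis for these genes, but limma's camera gave p = 4.32e-05 with the preset correlation and p = 0.129 with an estimated correlation, which leaves it open.

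In IMF17, features of the neochromosome outside the yeast annotation lay closer in log2 FPKM to a neighbour of the same strand (mean absolute difference 0.757, 73 pairs) than to a neighbour of the opposite strand (2.81, 32 pairs). The difference was -2.06 (permutation p = 1e-05, the smallest that 100000 resamples can give) and -1.64 without the highest pair of features. Neighbouring pairs share features and are not independent. Some same-strand pairs are by name parts of the same gene, such as pepN_1 and pepN_2, which overlap. Others lie in the quiet stretch from 118510 to 131296, where values near 0 keep differences small. The closeness is in part set by these pairs, and the test was not repeated without them. Transcripts that run through several features of a strand may be one source of this, as a hypothesis.

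Glycolytic genes were higher in IMF17. Against a scaling shift common to all genes stands the median log2 fold change, 0.48 for the 13 genes and -0.07 over all tested features. Rescaling moves all genes nearly alike, by 0.0663 upward under median ratio. The median of the 13 genes, 0.54 at the lower of both rescalings, could therefore only rise and is no separate test. An equal gain in gene dose as the whole cause is argued against by PFK1, at -0.38. Position on the neochromosome, sequence differences between the strains' copies, such as in promoters, and unequal mapping to the IMF17 assembly go with the strain and were not tested.

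General stress genes were higher and ribosomal protein genes lower in IMF17. With any one library left out at least 20 of the 25 stress genes were called higher, against a single library as the source. Both rescalings moved log2 fold changes upward. They left the ribosomal protein median no closer to 0 than -0.12, against scaling as the whole cause for those genes. For the stress genes they could only raise the median, from 0.81 to at least 0.88, and are no test of scaling. Against a shift common to all genes stands the median over all tested features, -0.07. The ribosomal protein list reached a lower camera adjusted p in a grouping that mixed the strains (5.27e-34) than in the comparison of strains (2.27e-15). That grouping keeps part of the strain difference, and no test within a strain was run. A later growth stage of the IMF17 cultures could not be told apart from an effect of strain: the gluconeogenesis list had a median of 0.35, FBP1 and PCK1 did not pass, and growth rate and glucose were not analysed here.

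The 2-micron plasmid genes had no reads in IMX2109. At the share seen in IMF17, 49702 reads would have been counted there, which argues against depth. A 2-micron plasmid of other sequence that could escape mapping stays open, since 0 of the 4 genes had a read and no value here bounds how much of its sequence would map.

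The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Mixed splits also place both strains in each group, so that the strain difference widens the spread within groups and holds gene calls down. Their gene counts therefore do not show how many calls would arise without a strain difference. The comparison of strains gave 2029 changed genes and the highest other split 0 (limma; 204 at an unadjusted p under 0.05, against 2520), 130 and 0 for changes of at least 2-fold, and 22 and 20 for lists, so that 1 split of the 10 was as large in each case. For chromosomes the values were 0 and 0, and all 10 splits were as large. Where lists were called in mixed splits, the strain difference that these keep in part may be one source. Of the 22 lists, 14 had their lowest adjusted p in the comparison of strains, but only 1 was called in no mixed split. With 22 against 20 the list count says little by itself. The 0 lists called with an estimated correlation do not settle the matter. Phosphate response, with an estimate of -0.0251 below the preset 0.01, also lost its call, and fry called 29 lists.

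The median, the mean and the camera direction differed in sign for lists outside the threshold, namely pentose phosphate (median -0.08, mean 0.32, camera up), histidine synthesis (-0.13, 0.03, down), haploid-specific genes (-0.05, 0.00317, up), zinc and copper (-0.04, -0.02, up), nitrogen catabolite repression (-0.10, 0.05, down), markers and integration sites (-0.13, 0.20, down) and silencing (-0.04, -0.05, up).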
